A study of Homo sapiens with 8 samples.

How the data were processed

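RNA was measured on 8 arrays, 4 of quiescent (pyronin Y dull) and 4 of cycling (pyronin Y bright) cells sorted from RL aggregates grown for 14 days. Groups and sample numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cRNA was made with a one-cycle Affymetrix protocol. Per the submitters' processing notes the values come from MAS5, whose version is not given in the sources used here. The deposited values are MAS5 intensities on a linear scale, with 62 control probe sets on each array. From the values, each array had been scaled by the authors to a mean of 500.1 after trimming 2% from each end. Present or absent calls were not used here, so a dim value cannot be told from background. All arrays were thus set to the same average, and a difference between groups is relative to the other transcripts on the array and not an amount per cell. Cells sorted for dim pyronin Y were selected for low RNA content.

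Intensities under 1 were set to 1 and taken to log2. The array medians of log2 values differed by 0.657. Because that exceeded the limit of 0.5 set before the data were examined, the arrays were centred on their medians for the tests described first. The deposited scaling and quantile normalization stand beside them. Probe sets were named through the platform annotation, which can be old. It listed 42898 probe sets, 41097 with 1 gene symbol and 1801 with several, and 11777 were unlisted, controls included. Entrez identifiers of 41043 were matched to RefSeq genes of assembly GRCh38.p14, which was used for names only, and no symbol changed. Probe sets with several symbols or none were not named. Each of the 19775 genes was represented by its brightest probe set over all 8 arrays. Genes whose mean log2 value lay under the median of all non-control probe sets, an intensity of 83.3, were left out, which removed 8097 and kept 11678. No column of values was left unused.

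Quiescent and cycling arrays were compared with lmFit and eBayes (trend and robust) of limma 3.58.1 in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 differences are quiescent minus cycling. Intensities are given as mean ± SD of the deposited values, and log2 differences as centred unless stated. Gene lists were compared with the other genes by camera at a preset correlation of 0.01, for lists with at least 5 measured members, and again with an estimated correlation. Control probe set ratios, array medians and list means were compared by two-sided exact permutation tests over all 70 assignments, with a smallest possible p of 0.0286. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

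The design, the alternatives, the rule for named genes and 34 gene lists were fixed before the data were examined. The lists cover S phase, G2 and M phase, histones, CDK inhibitors and quiescence regulators, ribosome biogenesis, ribosomal proteins, translation, MYC-linked growth, hypoxia, glycolysis, oxidative phosphorylation, lipid synthesis, stress responses, p53 targets, apoptosis, lysosome, B cell states, antigen presentation, interferon, NF-kB, immediate early genes, detoxification, adhesion, DNA repair, splicing, proteasome, reference genes and markers of other cell types. Named genes are the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, 19 fixed genes whatever their result, up to 4 members of each list that passed and up to 2 called members of each list that did not. Further members are named where few moved, and these were chosen after their values were seen. Of the fixed genes 1 had no probe set with a single symbol and is not analysed here, and 1 did not pass the filter. Some list members likewise had no such probe set. Of the 125 genes named by this rule, 67 had several probe sets that passed the filter. In 1 of these another probe set was called in the opposite direction. In some, such as NDUFS1, U2AF1 and MYBL1, the dimmer probe sets were not called.

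The gene and list tests were tried on simulated data for the 11678 genes, with 200 changed, as many up as down. In the data 4121 were called, most of them lower. In the simulation the gene test recovered 95% of genes changed 4-fold and 57% of those changed 2-fold, with 7 false calls and the right sign for all genes recovered. A list shifted by 0.5 was called and 0 of 30 random lists were. The simulated genes varied independently of each other, whereas the lists tested had estimated correlations of 0.047 to 0.824. The simulation thus does not show how the list test behaves for correlated genes. It began from values already centred and filtered, with 1 probe set per gene. The array centring, the filter and the choice of probe set were therefore not tested by it. Alternatives tried were no filter and a stricter filter at the 75th percentile, quantile normalization, the deposited scaling, adding 32 before the log, no intensity trend, array weights, a block for sample number, the mean of a gene's probe sets, all probe sets, and leaving out each array. Scaling to hybridization controls, centring on the genes tested, list tests with the deposited scaling and list means relative to all genes were added after seeing the data.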

Results

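The data compare resting with dividing cells of RL, an established human B lymphoma cell line that carries the translocation joining BCL2 to the immunoglobulin heavy chain locus. The cells had been grown for 14 days as multicellular aggregates and stained with pyronin Y, a dye that binds RNA. Cells with dim staining were sorted as quiescent and cells with bright staining as cycling. Total RNA of each fraction was hybridised to Affymetrix human expression arrays, with 4 quiescent and 4 cycling arrays. The question was which transcripts differ between resting and dividing cells of such aggregates. The labels do not say whether samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. After the authors' scaling each array had a trimmed mean intensity of 500.1, and array medians ran from 72.2 to 113.8.

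Relative to the other transcripts on the arrays, genes that copy DNA and carry out mitosis were far lower in quiescent cells. A smaller set was higher, which includes the CDK inhibitor CDKN1B, TXNIP and hypoxia-responsive genes. Of 11678 genes tested with limma, 327 were higher and 3794 lower in quiescent cells at an adjusted p under 0.05 after centring of the arrays on their medians. With the scaling as deposited, 1431 were higher and 1803 lower, so that 44.2% of the called genes were higher in place of 7.9%. With quantile normalization, 1233 were higher and 1914 lower. Array centring shifts every log2 difference by the same 0.412, and the median difference of all genes tested was −0.331 centred, 0.08 as deposited and −0.036 after quantile normalization. Under all 3 of these scalings, 320 genes were called higher and 1648 lower. A change of at least 2-fold was reached by 114 higher and 1427 lower genes in the centred values, and by 109 and 470 genes in all 3 scalings. Cycling sample 2 lay closer to the quiescent arrays than the other cycling samples did, with a mean correlation across the genes tested of 0.945 against 0.913 to 0.932. Without it, 357 genes were higher and 4535 lower. Of 33 gene lists tested with camera at a preset correlation, 5 passed as higher and 10 as lower relative to the other genes, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05.

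**Figure D1:**
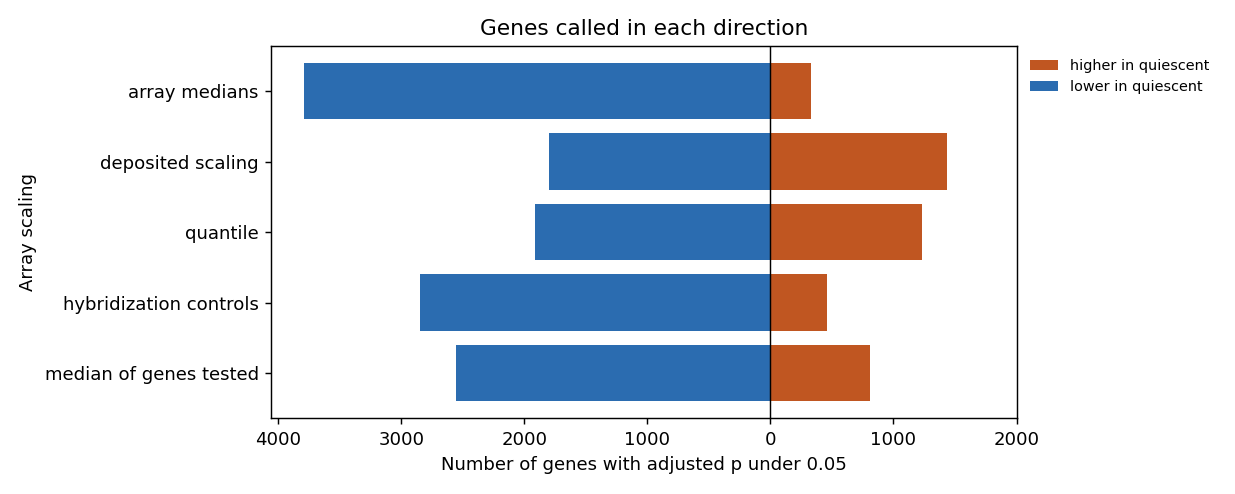
Number of genes with an adjusted p under 0.05 (horizontal axis) that were lower (bars to the left) or higher (bars to the right) in quiescent cells under 5 array scalings (vertical axis). Higher genes numbered 327 with array medians and 1431 with the deposited scaling.

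All 43 measured S phase genes and all 53 measured G2 and M phase genes fell in quiescent cells, and all of both did so when adjusted over the list alone. The median log2 difference was −2.07 for S phase and −2.28 for G2 and M phase, or −1.74 and −1.95 relative to the median of all genes. As deposited, 39 and 50 of them were called lower. TOP2A, which untangles DNA, fell from an intensity of 4783 ± 512 (SD, n = 4) to 540 ± 262 (SD, n = 4). MKI67, the proliferation marker, fell from 1899 ± 388 to 362 ± 188 and CCNB1, the mitotic cyclin, from 6334 ± 957 to 1358 ± 412. PCNA, the clamp of DNA polymerase, fell from 8709 ± 1401 to 2704 ± 870. CDK1, TPX2, CENPF and AURKA of the mitotic list fell, with log2 differences of −2.50 to −3.23. FEN1, CDC6, DSCC1 and MCM6 of the S phase list fell, with −2.53 to −3.47. The camera test of both lists against all other genes gave adjusted p = 1.95e-23 for S phase and 5.76e-29 for G2 and M phase at a preset correlation. With an estimated correlation, adjusted p = 0.535 for both, and the unadjusted p were 0.0396 and 0.0295. The log2 ratio of the 3′ to the 5′ ACTB control probe sets, a sign of RNA quality, also differed, at 2.02 ± 0.20 on cycling and 2.56 ± 0.18 on quiescent arrays (n = 4 each, two-sided exact permutation p = 0.0286, adjusted over 7 array measures 0.04). That p is the smallest the 70 assignments allow. The ACTB ratio of 3′ to middle probe sets and the GAPDH ratio of 3′ to 5′ were also higher, by 0.31 and 0.16 (exact permutation p = 0.0286 each, adjusted 0.04), and the GAPDH ratio of 3′ to middle differed by 0.004 (p = 0.914). This difference in the ACTB ratio lies between the same arrays as all gene groups described here.

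**Figure D2:**
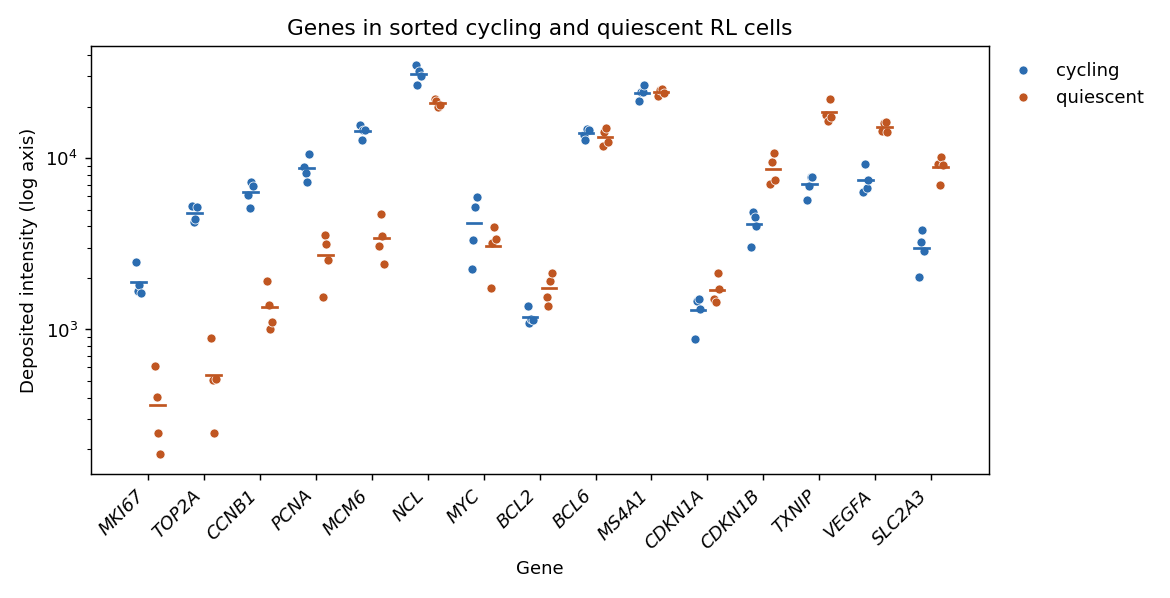
Deposited intensity of 15 genes on a log axis (vertical) for 4 cycling and 4 quiescent arrays per gene (points), with the group mean as a line. MKI67, TOP2A, CCNB1 and PCNA are lower on every quiescent than on every cycling array, while MS4A1 and BCL6 overlap.

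The 10 largest falls among genes whose groups did not overlap were CDC45, PBK, RRM2, ZWINT, FOXM1, EXO1, TYMS, HJURP, TRIP13 and DTL, and 6 of them belong to the S phase or mitotic lists. CDC45, a part of the replicative helicase, fell from 1307 ± 292 to 77.2 ± 54.6, a log2 difference of −4.77 (SE 0.50, limma adjusted p = 4.45e-05). FOXM1, a transcription factor of the mitotic programme, fell by 3.81 on the log2 scale, and the thymidylate synthase TYMS fell by 3.76. The quiescent means of CDC45 and EXO1 (62.4) lay under an intensity of 100. FOXM1, HJURP, TRIP13 and DTL were under 100 on some quiescent arrays. The size and rank of the falls of all these genes thus rest on dim values. The 10 largest rises were DEPP1, WFDC21P, MIR181A2HG, LRP2BP, ENAM, PSD3, APOL4, GAB2, ZNF276-AS1 and YPEL4. DEPP1 rose from 135 ± 111 to 948 ± 212, a log2 difference of 2.87 (SE 0.60, limma adjusted p = 4.99e-03). For 8 of these 10 the cycling mean lay under an intensity of 100, and DEPP1 and PSD3 were under 100 on some cycling arrays, so that the size and rank of all 10 rises rest on dim values. PSD3 no longer passed without quiescent sample 2, quiescent sample 3 or cycling sample 4.

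DNA repair genes fell with the replication genes, 25 of 31 measured against 1 higher, and 26 were lower adjusted over the list alone and 21 as deposited. CHEK1, the checkpoint kinase, fell from 3206 ± 481 to 514 ± 133, and BRCA1, PRKDC and FANCB fell as well. ATM, the kinase that responds to DNA breaks, was the 1 member that rose, by 0.69 on the log2 scale. The list passed camera at adjusted p = 2.6e-07, and at adjusted p = 0.535 with an estimated correlation it did not. Of 20 replication-dependent histone genes, 10 fell and 1 rose, with 11 and 1 adjusted over the list alone and 8 and 2 as deposited. H1-5 fell from 3274 ± 842 to 415 ± 46.1 and H3C2 from 1082 ± 206 to 148 ± 46.2, whereas H2BC21 rose from 91.8 ± 37.8 to 262 ± 66.0. The histone list as a whole did not pass (camera adjusted p = 0.135, and 0.798 with an estimated correlation), and passed as lower as deposited (adjusted p = 0.0439).

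Genes for building ribosomes and proteins were lower in quiescent cells. In the ribosome biogenesis list 55 of 63 measured members fell and 1, TAF1D, rose, and 57 fell adjusted over the list alone. As deposited, 42 were lower. BYSL, a factor of the small ribosomal subunit, fell from 1752 ± 328 to 593 ± 13.8, and MRTO4, RRP15 and the RNA polymerase III subunit POLR3G fell by 1.61 to 1.79 on the log2 scale. NCL, the nucleolar protein nucleolin, fell by 0.97 (adjusted p = 2.29e-04), and NPM1 fell by 0.42 at its brightest probe set, which differed by −0.009 as deposited and did not pass there. Its 2 other probe sets had log2 differences of −1.03 (limma adjusted p over all probe sets 5.83e-04) and −1.22 (7.71e-05). Of the translation factors and tRNA synthetases, 29 of 32 fell, among them EIF2B3, EIF2S1, FARSB and RARS1, and 30 did so adjusted over the list alone and 19 as deposited. Of the genes linked to MYC, 22 of 28 fell, with RANBP1, PHB1, SRM and MTHFD1 down by 2.08 to 2.51, and 23 adjusted over the list alone and 19 as deposited. MYC itself measured 4172 ± 1691 on cycling and 3065 ± 936 on quiescent arrays and did not pass (log2 difference −0.82, adjusted p = 0.0931). The camera adjusted p were 2.76e-12, 2.6e-07 and 5.12e-08 for the 3 lists. With an estimated correlation, adjusted p = 0.535 for each. The cytosolic ribosomal proteins stood apart. Of 51 measured, 6 were lower and 45 were not called in the centred values, whereas 6 were higher and 0 lower as deposited, and none passed adjusted over the list alone. Their median was 0.08 above that of all genes. Their list did not pass in the centred values (adjusted p = 0.453), and passed in the opposite direction as deposited (adjusted p = 1.15e-03, or 0.909 for the centred values with an estimated correlation). Without cycling sample 2 it passed as lower in the centred values (adjusted p = 0.0229).

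Mitochondrial respiration, splicing and protein turnover genes fell together. Of 48 oxidative phosphorylation genes, 47 fell, all 47 of them also adjusted over the list alone, and 33 were called as deposited. ATP5MC1, a subunit of ATP synthase, fell from 1630 ± 353 to 551 ± 133, and COX6C, NDUFA9 and NDUFS1 fell by 1.34 to 1.66 on the log2 scale. Of 26 proteasome genes, all 26 fell, including PSMD1, PSMD14, PSMB2 and PSMD12, and 25 were called as deposited. Of 36 spliceosome genes, 33 fell, including SRSF3, SNRPD1 and U2AF1, and 35 did so adjusted over the list alone and 24 as deposited. HNRNPM also fell at its brightest probe set, but another of its 7 probe sets was called in the opposite direction. Of 15 heat shock chaperones, 10 fell, with HSPE1, FKBP4, HSPA4L and CHORDC1 down by 1.34 to 1.84, and 11 adjusted over the list alone, whereas 9 fell and 1 rose as deposited. The camera adjusted p were 3.48e-12 for oxidative phosphorylation, 6.67e-11 for the proteasome, 8.43e-10 for the spliceosome and 2.38e-03 for the chaperones. With an estimated correlation, adjusted p = 0.535 for each.

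The genes that rose included regulators of the resting state. In the list of CDK inhibitors and quiescence-associated regulators, 7 of 31 measured members rose and 2 fell, the same numbers adjusted over the list alone. As deposited, 13 rose and 2 fell. CDKN1B, which encodes the CDK inhibitor p27, rose from 4102 ± 799 to 8673 ± 1716 (log2 difference 0.67, SE 0.20, limma adjusted p = 0.0128), and without quiescent sample 3 it did not pass. TXNIP, an inhibitor of thioredoxin, rose from 7023 ± 966 to 18500 ± 2586. PIK3IP1, which restrains PI3 kinase, rose from 3737 ± 625 to 9636 ± 1790 and YPEL3 from 1993 ± 283 to 5244 ± 1197. KLF2, MXI1 and PDCD4 rose too, while RBL1 and MXD3 fell. CDKN1A, which encodes p21, did not pass (log2 difference 0.001, SE 0.21, and 0.41 as deposited with adjusted p = 0.122), nor did RBL2 (0.15, SE 0.20, and 0.56 as deposited with adjusted p = 0.0638). The list passed camera as higher than other genes (adjusted p = 2.21e-06), and not with an estimated correlation (adjusted p = 0.535).

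Of 27 measured hypoxia-responsive genes, 8 rose and none fell, and 6 rose adjusted over the list alone. VEGFA, the angiogenic growth factor, rose from 7438 ± 1273 to 15250 ± 1093. SLC2A3, a glucose transporter, rose from 2992 ± 754 to 8859 ± 1360, NDRG1 from 2690 ± 643 to 7036 ± 1931 and ANKRD37 from 1366 ± 215 to 3333 ± 641. ADM, MXI1, KDM3A and BHLHE40 also rose. As deposited, 14 were higher. The list passed camera (adjusted p = 1.29e-05), and not with an estimated correlation (adjusted p = 0.535). The glycolysis list did not pass (adjusted p = 0.455, or 0.905 with an estimated correlation), and of its 18 members 2 rose and 4 fell, the same numbers adjusted over the list alone. SLC2A3 rose and PFKM, a phosphofructokinase, fell by 0.88. As deposited 4 rose and 2 fell, and the list passed as higher (adjusted p = 0.0388).

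The NF-kB, immediate early and interferon lists also passed camera as higher than other genes, with few members called in the centred values. As deposited, 7 NF-kB, 5 immediate early and 3 interferon genes were called higher and none lower. In the NF-kB list 1 of 19 members rose, also adjusted over the list alone, the chemokine receptor CCR7, from 225 ± 99.4 to 628 ± 202 (camera adjusted p = 0.0101, and adjusted p = 0.535 with an estimated correlation). SOD2, CD40 and REL had log2 differences of −0.49, −0.36 and 0.41 and did not pass. Of 21 immediate early genes, 2 rose and 2 fell, with 2 and 1 adjusted over the list alone. RGS1 rose from 130 ± 48.8 to 688 ± 325 and CD69 from 273 ± 102 to 1042 ± 438, while NR4A1 and EGR3 fell (camera adjusted p = 0.0231, and adjusted p = 0.798 with an estimated correlation). The interferon list had 0 of 35 members called higher and 2, IFITM3 and IFITM2, called lower, and none adjusted over the list alone (camera adjusted p = 5.47e-05, and adjusted p = 0.798 with an estimated correlation). BST2 and PARP14 had log2 differences of −0.48 and 0.42 and did not pass. The immediate early and interferon lists no longer passed without cycling sample 1 (adjusted p = 0.238 and 0.0707), and the immediate early list also not without quiescent sample 3 or 4.

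**Figure D3:**
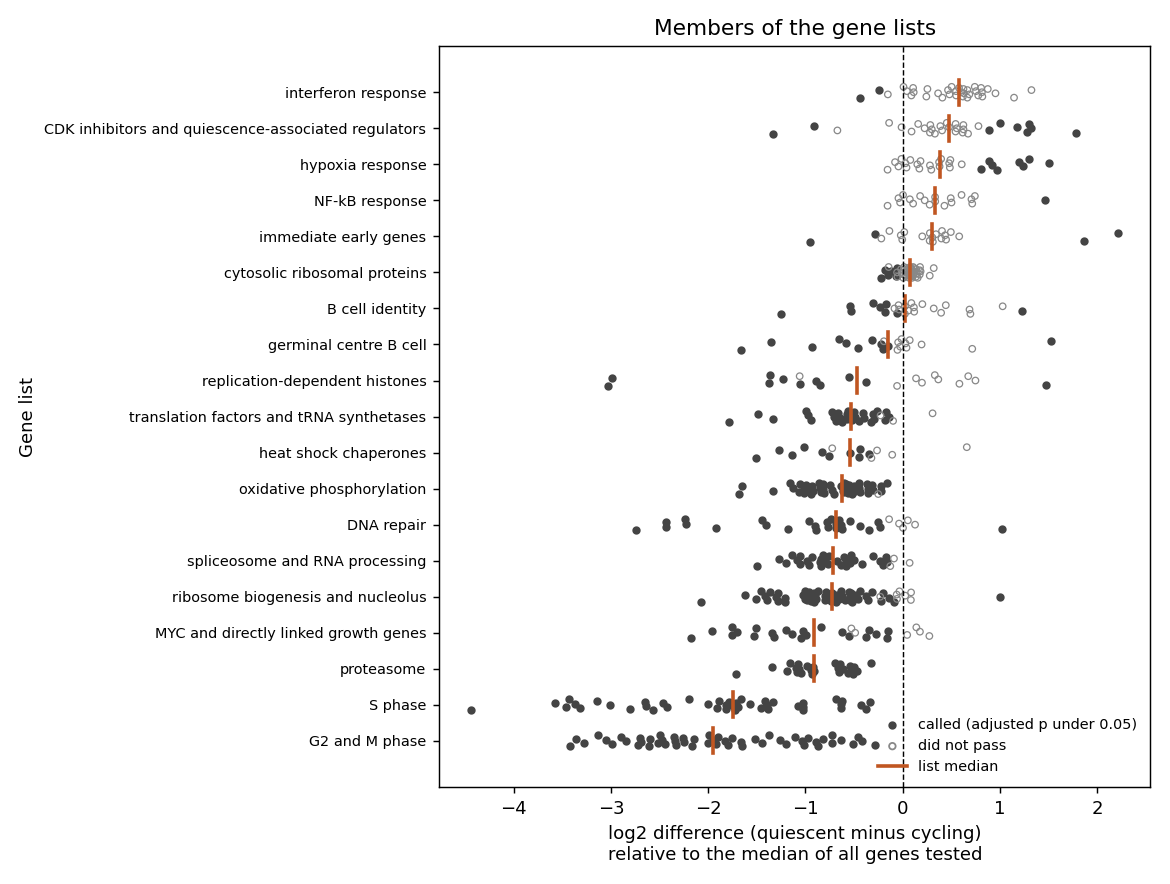
Log2 difference between quiescent and cycling cells, minus the median of all genes tested (horizontal axis), of each measured member of 19 gene lists (vertical axis), as filled points where the member passed and open points where it did not, with the list median as a bar. The S phase and mitotic medians lie at −1.74 and −1.95, and that of the cytosolic ribosomal proteins, whose list test turned direction between scalings, at 0.08.

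B cell and survival genes went both ways. Of 25 B cell identity genes, 1 rose and 8 fell, also adjusted over the list alone, whereas 6 rose and 1 fell as deposited. FCRLA fell from 5429 ± 887 to 2391 ± 230 and CD24 rose from 1384 ± 388 to 3338 ± 601. MS4A1, which encodes CD20, measured 24170 ± 2083 on cycling and 24460 ± 1072 on quiescent arrays, with log2 differences of −0.39 centred (adjusted p = 0.0487), 0.02 as deposited and 0.06 after quantile normalization. BCL6, the germinal centre repressor, likewise had −0.49 centred (adjusted p = 0.0346), −0.07 as deposited and 0.05 after quantile normalization. Of 21 germinal centre genes, 1 rose and 10 fell, with 1 and 11 adjusted over the list alone and 2 and 6 as deposited. MYBL1 and the ectoenzyme CD38 fell by 2.00 and 1.68 on the log2 scale, and the chemokine receptor CXCR4 was the 1 that rose, from 4684 ± 1693 to 13820 ± 3501. Of 11 plasma cell genes, 7 fell, also adjusted over the list alone, including TNFRSF17 and FKBP11, and 4 fell and 1 rose as deposited. PRDM1 did not pass the intensity filter. Of 21 BCL2 family and apoptosis genes, 1 rose and 8 fell, also adjusted over the list alone, whereas 8 rose and 2 fell as deposited. HRK, which promotes cell death, rose from 238 ± 139 to 914 ± 211, and BID and BIK fell. BCL2 measured 1186 ± 127 and 1752 ± 349 (log2 difference 0.13, adjusted p = 0.64), and passed as deposited (0.55, adjusted p = 0.0228). Of its 2 other probe sets that passed the filter, 1 was called higher in the centred values (0.95, limma adjusted p over all probe sets 0.0456) and the other was not (0.22). CCND3 fell by 0.73 and did not pass as deposited, and CCND2 did not pass (−0.19, SE 0.37). None of these 4 lists passed camera on all 8 arrays in the settings described first, with adjusted p = 0.654 for B cell identity, 0.12 for the germinal centre, 0.15 for plasma cells and 0.456 for apoptosis. The germinal centre list passed as lower without cycling sample 2 (adjusted p = 0.0341). On all 8 arrays with an estimated correlation, adjusted p = 0.909 for B cell identity, 0.798 for the germinal centre and plasma cells and 0.888 for apoptosis.

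The other fixed lists did not pass camera in the centred values of all 8 arrays in the settings described first. Antigen presentation passed as higher without quiescent sample 2 (adjusted p = 0.0219) or cycling sample 3 (0.0437), and the stress response (0.0442) and reference genes (0.0261) passed as lower without cycling sample 2. On all 8 arrays with an estimated correlation, adjusted p = 0.874 for antigen presentation and 0.798 for the other 2. In the antigen presentation list (adjusted p = 0.15) 1 of 26 rose and 4 fell, also adjusted over the list alone, with PSMB8 and PSMB9 lower. As deposited 10 rose and 1 fell, and the list passed as higher (adjusted p = 0.014, whereas the centred values gave adjusted p = 0.874 with an estimated correlation). Of 22 drug efflux and detoxification genes (adjusted p = 0.315) 11 fell, also adjusted over the list alone, with GSTO1 and GCLM down by 1.09 and 1.07, and 5 fell and 2 rose as deposited. Of 20 p53 targets (adjusted p = 0.455) 1, TP53INP1, rose and 6, TIGAR among them, fell, and of 33 autophagy and lysosome genes (adjusted p = 0.549) 2 rose and 10, GLA and ATG5 among them, fell, with the same numbers adjusted over each list alone. As deposited these turned to 6 higher and 1 lower p53 targets and 9 higher and 2 lower autophagy and lysosome genes. Of 25 cholesterol and fatty acid synthesis genes (adjusted p = 0.612) 10 fell, including ACLY and PMVK, and of 28 stress response genes (adjusted p = 0.12) 15 fell, including PSAT1 and CALR, also adjusted over each list alone. As deposited 5 were higher and 4 lower in the first of these lists, and 1 higher and 5 lower in the other. Of 17 adhesion and matrix genes (adjusted p = 0.585) 4 fell, including ITGB7 and ICAM3, and 3 adjusted over the list alone, whereas 3 rose and 1 fell as deposited. Among 13 reference genes (adjusted p = 0.131) 7 fell, also adjusted over the list alone, with HPRT1 down by 1.59 and SDHA by 0.95, and 3 rose and 2 fell as deposited.

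Few markers of other cell types were called. None of 6 T and NK cell markers (camera adjusted p = 0.91) and none of 5 erythroid and platelet markers (adjusted p = 0.135) was called, though the erythroid and platelet list passed as higher without cycling sample 2 (adjusted p = 0.0341, and adjusted p = 0.535 on all 8 arrays with an estimated correlation). Of 7 fibroblast and endothelial markers (adjusted p = 0.585) 1, THY1, fell from 1270 ± 105 to 553 ± 54.1. With 4 monocyte and macrophage markers measured, that list was not tested as a set, and none of the 4 was called. Relative to the median of all genes, the erythroid and monocyte list means were 0.51 and 0.48 higher on quiescent arrays (two-sided exact permutation p = 0.143 and 0.0857). LCK, a kinase of T cells, was bright in both groups, at 8167 ± 693 on cycling and 8541 ± 1460 on quiescent arrays. The next brightest T and NK cell marker, PRF1, measured 348 on cycling and 356 on quiescent arrays, and the T cell marker CD3E 123 and 103.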

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

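The tests of centring, of messenger RNA content, of RNA from other cells, of the other 3 ACTB and GAPDH ratios and of other splits for the 2-fold count were chosen only after the results were seen. The tests of the ACTB ratio and of other splits for all called genes and for lists were set down beforehand.

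Single arrays lay far from the other 3 of their group, with a gap to the nearest one above Dixon's 95% critical value, in 29 of 250 groups of gene values, 3 of 68 groups of list means and 1 of 14 groups of array measures. Chance gives about 1 in 20. Cycling sample 2 made up 16 of these 33 and was the lowest cycling array in each. Gene values and list means were centred for this check. Its array median, 6.62 on the log2 scale, was above the 6.17 to 6.31 of the other cycling arrays, so centring lowered its values most. As deposited, GCLM measured 1179 on it against 1259 to 1445 on the other cycling arrays. Gaps were not computed on deposited values, so these flags may come in part from centring. The gap over the range was 0.904 for CDC45, 0.907 for FEN1, 0.96 for CDC6, 0.833 for MCM6, 0.932 for TPX2, 0.918 for POLR3G, 0.892 for EIF2B3, 0.851 for FARSB, 0.892 for SRM, 0.845 for ACLY, 0.832 for PMVK, 0.906 for PSAT1, 0.967 for CD38 and 0.898 for GCLM. It was 0.889 for the mean of the G2 and M phase list and 0.881 for that of the MYC-linked list. The cell cycle lists, relative to the array's median gene, averaged 1.61 on cycling sample 2 against 1.87 to 2.10 on the other cycling arrays and −0.21 to 0.35 on the quiescent arrays. Its ACTB 3′ to 5′ log2 ratio was 2.26, against 1.80 to 2.09 on the other cycling arrays.

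Cycling sample 1 was lowest for PSD3 (0.835), VEGFA (0.876), CD69 (0.872) and the list of CDK inhibitors and quiescence regulators (0.836), and highest for CCND2 (0.895). As deposited, VEGFA measured 6353 on cycling sample 1 and 6726 on cycling sample 3, and was highest on cycling sample 2 at 9221. Cycling sample 4 was lowest for NDRG1 (0.865). Quiescent sample 1 was highest for TPX2 (0.916) and ICAM3 (0.862) and lowest for EGR3 (0.938). Quiescent sample 2 was highest for RRP15 (0.857) and SRSF3 (0.862) and lowest for CD40 (0.987) and FANCB (0.853). Quiescent sample 3 was highest for CCND2 (0.93). Quiescent sample 4 was lowest for PMVK (0.858) and highest for BIK (0.844) and for the GAPDH 3′ to 5′ ratio (0.955).

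Signals outside the main comparison also differed. The poly-A controls, added to RNA before labelling, were higher on quiescent arrays by 0.413 on the log2 scale (8.83 ± 0.02 against 8.42 ± 0.08, n = 4 each, exact permutation p = 0.0286). The hybridization controls were higher by 0.26 (exact permutation p = 0.0571). Of 5048 tested probe sets without a single gene name, 694 were called lower and 423 higher in the centred values, and 276 lower and 1240 higher as deposited.

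The first pattern weighed is that 3794 genes were called lower and 327 higher after centring on array medians. Centring on the genes tested in place of all probe sets gave 24% higher calls in place of 7.9%, but it adds the same 0.24 to every log2 difference, so that it sets this balance and does not tell which is right. A candidate explanation is less messenger RNA per amount of total RNA in quiescent cells, for which the poly-A controls would rise more than the hybridization controls. They did by 0.153 (exact permutation p = 0.0857), which leaves it open. The sorted state itself stays open as a biological explanation, untested, since pyronin Y selects on RNA content.

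Among the 35 splits of the 8 arrays, 1, the real one, gave as many as 4121 called genes, and the highest other gave 12. For genes changed at least 2-fold, 1 of 35 splits gave as many as 1541, and the highest other gave 12. Both counts thus belonged to the real split alone, the smallest share that 35 splits allow. Every other split mixes the sorted groups, so the group difference adds to its error and holds its count down. The only mixed split with any call, the one that gave 12, set samples 1 and 2 of both groups against samples 3 and 4. The splits do not show what chance alone would give, nor separate the sort from other differences between the fractions. For the number of gene lists, chance likewise cannot be excluded. Of the 35 splits, 10 gave at least the 15 lists that passed camera at the preset correlation, and the highest other gave 22. All 9 other splits that reached 15 kept 3 cycling arrays together, and the 18 splits with 2 cycling arrays on each side gave at most 11.

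The second pattern weighed is that cell cycle genes were lower on the arrays with the higher ACTB 3′ to 5′ ratio. With that ratio as a covariate the difference of the 96 cell cycle genes, relative to the median gene, was −1.67 (95% interval −2.59 to −0.75). Without it the difference was −1.80 (−2.23 to −1.38). With the other 3 ACTB and GAPDH ratios, 1 at a time, it was −1.60, −1.47 and −1.82 (95% intervals all under −0.72). Both ACTB ratios and the GAPDH 3′ to 5′ ratio were higher on every quiescent than on every cycling array. Adjusting for them extends a slope beyond the values the groups share, and cannot separate the group from RNA quality. The GAPDH 3′ to middle ratio did not differ between the groups, so adjusting for it tests nothing. These fits therefore leave degradation open. RNA from other cells was first judged by the brightest marker, and the level set for it was reached by LCK alone, at 1.49 times the median B cell gene, whereas the highest list median of the 5 most abundant markers, a test chosen because of that outcome, was 0.0451, but levels of different probe sets are not on a common scale and neither decides. Such RNA would lower B cell identity genes as much as cell cycle genes, and the changes of these lists differed by 1.97 (95% interval 1.41 to 2.53, two-sided exact permutation p = 0.0286), which argues against other cells as the cause of the fall, while a small share stays open. The sorted state, quiescent against cycling, stays open as a biological explanation, untested.

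Among markers of other cells, LCK measured 8167 on cycling and 8541 on quiescent arrays, THY1 1270 and 553, TYROBP 268 and 420, PRF1 348 and 356, COL6A2 158 and 263, and ACTA2 229 and 259. No marker list passed camera as higher on all 8 arrays in the settings described first, whereas the erythroid and platelet list did without cycling sample 2 (adjusted p = 0.0341, and adjusted p = 0.535 on all 8 arrays with an estimated correlation). The cells came from aggregates of the RL cell line, and the labels name no gate that would remove other cells.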

How the results depend on the processing

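The tests with hybridization controls, with centring on the genes tested, of lists and list means with the deposited scaling and of list means relative to all genes were chosen only after seeing the data. Counts of called genes, in each direction and at least 2-fold, stayed within 1.5 times of the first values with no filter, 32 added before the log, no intensity trend, array weights and the mean of a gene's probe sets. Quantile normalization gave 1233 higher and 1914 lower genes and 871 changed at least 2-fold (262 higher, 609 lower), and the cause was not tested. The deposited scaling gave 1431, 1803 and 904 (400, 504), where every log2 difference is larger by 0.412 by construction. Testing all probe sets gave 7670 called, 1165 higher and 6505 lower, with 2974 at least 2-fold (468, 2506), from more features tested. With the stricter filter 35 genes were at least 2-fold higher, from fewer genes tested. Centring on the genes tested gave 809 higher genes, and 244 higher and 800 lower at least 2-fold. Genes at least 2-fold higher numbered 177 with hybridization controls. These last 2 scalings also move every log2 difference by a constant. Dim genes are limited by signal over background, which the values do not give.

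With an estimated correlation 0 lists passed camera (0 higher, 0 lower), and 2 had an unadjusted p under 0.05. Lists passing as higher numbered 10 with quantile normalization and 8 with the deposited scaling. Without the filter, 4 lists passed that had not before and 1 no longer passed. With the mean of a gene's probe sets 1 list no longer passed. When genes in more than 1 list were left out, 1 list passed that had not before. The cytosolic ribosomal protein list turned to higher with quantile normalization (adjusted p = 0.00507) and the deposited scaling (0.00115), passed as lower without cycling sample 2 (0.0229), and reached at most 0.913 in the other settings. BCL6 turned to 0.051 with quantile normalization, and MS4A1 to 0.065 with it and 0.02 as deposited. List mean differences that turned positive with an exact p of 0.0286 were glycolysis (0.271, quantile), p53 targets (0.156 quantile, 0.184 deposited, 0.192 relative to all genes), apoptosis (0.202, deposited) and lysosome (0.179, relative to all genes). Other list means also turned positive, with an exact p over 0.05. The turns as deposited and relative to all genes follow from a constant added to every log2 difference. Those of quantile normalization, and of the ribosomal protein list test, have causes that were not tested.

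Leaving out single arrays gave 3251 to 4892 called genes, 221 to 357 higher and 2938 to 4535 lower, and 1356 to 2086 at least 2-fold (86 to 141 higher, 1215 to 1949 lower). It gave 13 to 20 lists, 3 (without cycling sample 1) to 6 as higher and 10 to 14 as lower. The ACTB ratio difference was 0.473 without quiescent sample 2 and 0.532 without quiescent sample 3 (exact p = 0.0571 each), against 0.55 on all 8 arrays. Sample numbers were not shown to pair the samples, since deviations correlated at 0.344, 0.196, 0.11 and 0.036, and cycling sample 4 and quiescent samples 3 and 4 did not correlate best with their own number. A fit with a replicate block called 465 higher and 4439 lower genes.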

Other observations

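The tests of a source shared by sample number and of what centring leaves were chosen only after the result was seen. The tests of the spread of all genes and of FOXO-responsive genes were set down beforehand.

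Interferon-stimulated genes varied more between arrays of a group than between groups. MX1, an antiviral GTPase, measured 990.7, 3046, 13580 and 13594 on cycling samples 1 to 4 and 2741, 3950, 15888 and 16420 on quiescent samples 1 to 4. IFI44L measured 762, 2993, 11204 and 12344 on the cycling and 4796, 5525, 18950 and 18858 on the quiescent samples. ISG15, a ubiquitin-like protein, measured 1034, 2398, 6387 and 7119 against 2288, 2509, 7023 and 7096. These genes were chosen after their values were seen. The mean of the 35 measured interferon genes was 10.10 ± 1.01 on cycling and 10.26 ± 0.74 on quiescent arrays (centred log2, n = 4 each, two-sided exact permutation p = 0.8). As deposited the difference was 0.58 (exact permutation p = 0.429). Within each sample number the deposited mean was higher on the quiescent array. It was 9.655 against 8.673 for sample 1 and 10.03 against 9.657 for sample 2. For samples 3 and 4 it was 11.129 against 10.652 and 11.071 against 10.583. Centring changes these differences, and the numbers were not shown to pair the samples. The permutation tests take the arrays as unpaired. In both groups the deposited mean was lower on samples 1 and 2 than on samples 3 and 4, and no cause of this was tested.

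The variation of the interferon genes may follow a source shared by the arrays of one sample number. Of the 24 ways to pair the cycling with the quiescent arrays, none gave a smaller mean difference between partners than pairing by number (0.216 log2). The pairing with samples 3 and 4 swapped tied with it. With that tie counted, pairing by number had rank 2 (exact p = 0.0833), which leaves this open. For array brightness, the SD over arrays of the mean of all genes, 0.0517 of that of the interferon mean, decides nothing, since the authors' scaling held it small. Centring left an SD of the interferon mean of 0.822 against 0.779 as deposited, a ratio of 1.06. The array medians had an SD of only 0.129 within groups, so centring could not have removed most of that spread, and the ratio tests nothing further. That small spread of the medians argues against brightness shared by all genes, as left after the authors' scaling, as the source of the interferon variation. No biological explanation was tested, because the labels give none for differences between sample numbers.

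A hypothesis was that genes described as responsive to FOXO transcription factors rose together, since DEPP1, TXNIP, KLF2 and CDKN1B had been seen to rise. A list of 31 other such genes was written before its test but after gene values had been seen, and 28 were measured. Of these 5 rose (PIK3IP1, RICTOR, MXI1, GABARAPL1 and ZBTB20), 1 (CAT) fell and 22 were not called, while 12 rose and 0 fell as deposited. PIK3IP1 rose from 3737 ± 625 to 9636 ± 1790 and RICTOR from 2839 ± 388 to 6514 ± 1094. The list passed the limma camera test as higher at the preset correlation (p = 2.72e-07), but with an estimated correlation p was 0.0611. It is not independent of the values described above, since 16 of the 28 genes, PIK3IP1 and MXI1 among them, also belong to fixed lists. The limma camera test of the other 12 genes at the preset correlation gave p = 7.54e-04, and 0.0697 with an estimated correlation. The hypothesis stays open, and no FOXO activity was measured.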
